A study of Mus musculus with 10 samples.

How the data were processed

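Polyadenylated RNA of the left ventricular posterior wall of mice aged 30 weeks was sequenced in 6 Mc4r knockout and 4 wild type libraries. Per the labels' protocols, frozen hearts gave total RNA, and 200 ng of it per sample, with an integrity number above 7, entered a stranded KAPA library preparation selected for poly(A). Per the submitters' processing notes, the tools named are bcl2fastq, TopHat2 2.1.0, Bowtie2, Cufflinks 2.2.1, Cuffnorm 2.2.1.1 and Cuffdiff 2.2.1.3, with the mouse build mm10. The notes give neither the role of each tool nor the gene annotation, and the strand setting is not given in the sources used here.

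The series holds 1 table of 24160 gene rows and 10 columns, 1 per library, and all its columns were used. The signal values deposited by the authors are read counts per gene divided by a size factor for each library, as the values themselves show. In each library nearly all values were whole multiples, within 0.1, of the value of 1 read (99.99 to 100% of the values above 0), and highly expressed long genes were not scaled down, so the values carry no division by gene length. They are called normalized counts here. Dividing by the value of 1 read gave back 4145033 to 6425785 reads per library, and the 10 most abundant genes held 11.8 to 12.9% of them. FPKM values had been assumed when the test was fixed. For a file of raw counts the plan named edgeR (quasi-likelihood) instead. The file holds size-factor-normalized counts, so the planned test on log2 values was kept. Count models on the recovered reads were run as alternatives, a choice made after the data were seen.

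Rows carry RefSeq transcript accessions, of which 24107 rows matched a gene symbol in a RefSeq gene table of GRCm38.p6, the assembly that mm10 also names. Coordinates come from that table and are 1-based. Of the matched rows 339 join several symbols, and 53 rows have no symbol. The mitochondrially encoded genes had no row in the table used here, so their list was not tested.

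Genotype was compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust) on log2(normalized count + 1), over all 10 libraries and without covariates. A gene was tested when its mean over the 10 libraries was at least 1, which left 14611 genes, and p-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Fold changes are on the log2(normalized count + 1) scale, knockout over wild type, which understates the change of low genes. Errors of fold changes are standard errors and errors of levels are SDs between libraries. Single values were compared with exact permutation tests over the 210 splits of the libraries.

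Before the data were examined, 41 gene lists of cardiac pathways and cell types were fixed, and 39 of them, each with at least 5 tested genes, were tested with camera at a preset correlation between genes of 0.01. Alternatives were camera with an estimated correlation, camera on ranks, and fry. The sex-linked genes served as a check of the libraries and were not tested as a list. Named genes follow a rule fixed at the same time. They are Mc4r, the 10 higher and the 10 lower genes with the largest absolute log2 fold change among those past the threshold, and up to 4 tested members with the smallest unadjusted p of each list described. Some genes that the rule takes are not reported here. Unnamed models, near-identical paralogs and rows joining several symbols were to be skipped among the largest changes, and 0 were skipped. Called genes within 10 Mb of Mc4r were compared with those elsewhere by Fisher's exact test.

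The procedure was tested on simulated data. Counts for the 14611 genes were drawn from the real means, dispersions and library sizes, with 50 genes changed at each of 4 fold sizes. All changed genes had a mean normalized count of at least 50, so detection of lower genes was not tested. The test found 48% of the 1.3-fold, 86% of the 1.5-fold, 98% of the 2-fold and 100% of the 3-fold changes, and 13 of its 179 calls were false (7.26%). With nothing changed, 0 of the 39 lists were called by camera, but the genes were drawn independently, so this does not test the list calls against correlated genes.

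Settings chosen for comparison in advance were other pseudocounts, filters and normalizations, limma without the trend and robust steps, library weights, a block for the replicate number, a permutation statistic per gene, and leaving out each library in turn. Added after the data were seen were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, though edgeR had been planned for raw counts. Removal of trends with transcript GC content and length was added too. So were fits without wild type replicate 2, which held lymphocyte transcripts, alone (edgeR) or together with knockout replicate 5, the highest in the atrial genes Myl7 and Sln (limma). Knockout replicate 6, with lower levels of both atrial genes, was kept. Also added were 3 gene lists: T-cell receptor signalling genes, B-cell and CD8 T-cell markers, and FoxO target genes. GC content and length came from GENCODE M21 transcripts, for 99.5% of the tested genes and 100% of the called genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.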

Results

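Messenger RNA of the posterior wall of the left ventricle was measured in mice that lack the melanocortin 4 receptor (Mc4r), a G-protein-coupled receptor best known for the control of food intake in the hypothalamus, and in wild type mice. The labels give 6 Mc4r knockout and 4 wild type libraries, all from C57BL6/J mice of 30 weeks bred from heterozygous parents and housed at 24 °C. The series describes a dilated cardiomyopathy after loss of the receptor, so the comparison asks which transcripts differ between the genotypes in ventricle. The number of reads assigned to genes ran from 4145033 in wild type replicate 3 to 6425785 in wild type replicate 4. The labels speak of mice but do not say in so many words that each library is a separate animal, so the p-values measure the spread between these samples.

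Mc4r itself, on chromosome 18 from 66857705 to 66860487 (GRCm38), was close to absent in both genotypes. It had 4 reads over the 6 knockout libraries and 2 over the 4 wild type libraries, with at most 2 in any library. The mean normalized count was 0.627 ± 0.975 (SD, n = 6) in the knockout and 0.481 ± 0.962 (SD, n = 4) in wild type, and an exact two-sided permutation test gave p = 0.833. At this depth the targeted gene therefore checks no label.

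The knockout ventricles differed from wild type in a small set of genes with moderate fold changes. The largest increase was in Lypd6, a membrane-anchored protein of the Ly6 family that binds nicotinic acetylcholine receptors, with 22.5 ± 7.18 normalized counts (SD, n = 6) in the knockout against 6.03 ± 3.79 (SD, n = 4) in wild type, a log2 fold change of 1.90 ± 0.35 (SE; limma with Benjamini-Hochberg adjustment, adjusted p = 0.00991). Chrna2, a subunit of those nicotinic receptors, rose by 1.44 ± 0.27 on the log2 scale (limma, adjusted p = 0.0118). Among ion channel genes, the inward rectifier potassium channel Kcnj14 rose by 1.55 ± 0.27 (adjusted p = 0.0038) and the sodium channel beta subunit Scn4b by 0.85 ± 0.11 (adjusted p = 0.00286). Scn4b was the most abundant of the 10 largest increases, at 1184 ± 162 normalized counts in the knockout and 656.5 ± 96.1 in wild type. Edn3, which encodes the peptide endothelin 3, rose by 1.44 ± 0.22 (limma, adjusted p = 0.00304).

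Complement C7 and the cationic amino acid transporter Slc7a1 led the genes that were lower in the knockout and held their call in each leave-one-out run. C7 fell from 119.5 ± 30.6 normalized counts (SD, n = 4) in wild type to 56.0 ± 12.4 (SD, n = 6), a log2 fold change of -1.07 ± 0.17 (limma, adjusted p = 0.00286), and Slc7a1 fell from 381 ± 33.7 to 216 ± 38.7, a log2 fold change of -0.83 ± 0.11 (adjusted p = 0.000622). Shld1, a subunit of the shieldin complex of DNA repair, fell by 0.72 ± 0.11 on the log2 scale (adjusted p = 0.00158), Tcp11l2 by 0.64 ± 0.08 (adjusted p = 0.000183), the coagulation inhibitor Tfpi by 0.57 ± 0.09 (adjusted p = 0.00158) and the endoplasmic reticulum phagy receptor Retreg1 by 0.55 ± 0.08 (limma, adjusted p = 0.00144). Ahrr, the repressor of the aryl hydrocarbon receptor, had a log2 fold change of -1.15 ± 0.22 (adjusted p = 0.0112).

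In all, 67 of 14611 genes passed an adjusted p of 0.05 (limma with Benjamini-Hochberg adjustment), 42 higher and 25 lower in the knockout, while 1403 had an unadjusted p below 0.05 against 731 expected by chance. The fold change was below 2 for 58 of the 67 genes, and the median absolute log2 fold change was 0.54. Over all 14611 genes, the knockout and wild type libraries did not overlap in 333 (2.28%), against 0.952% from a chance order of 6 and 4 libraries. The count depended on the model. It was 0 without limma's trend and robust steps (1290 at an unadjusted p below 0.05) and 122 by DESeq2. By edgeR, the test planned for raw counts, 50 genes passed, 30 higher and 20 lower. The count also depended on single libraries. It was 37 without knockout replicate 1, 29 without knockout replicate 2, 44 without knockout replicate 3, 31 without wild type replicate 3 and 26 without wild type replicate 4, and it rose to 118 without wild type replicate 2. The number of higher genes also dropped from 42 to 27 without knockout replicates 4 or 6.

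**Figure D1:**
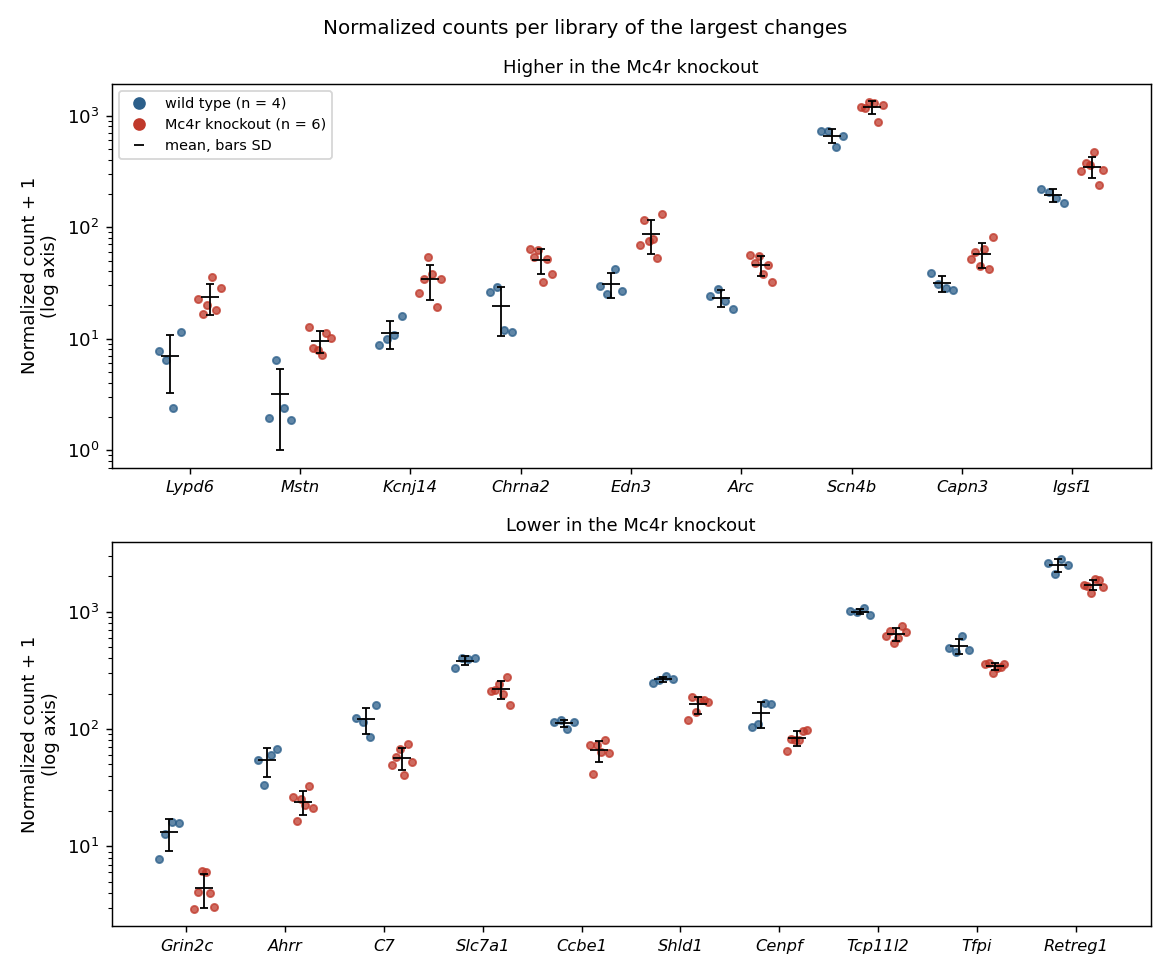
Normalized counts plus 1 on a log axis for genes named among the 10 largest increases (top) and 10 largest decreases (bottom) past an adjusted p of 0.05. Each point is a library (blue, 4 wild type; red, 6 Mc4r knockout) and the bars give the mean and SD, with the lower bar ended at a count of 0; Lypd6 averaged 22.5 in the knockout against 6.03 in wild type.

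Of the 20 genes with the largest changes, 10 kept their call whichever library was left out. These were Lypd6, Kcnj14, Edn3, Scn4b, C7, Slc7a1, Shld1, Tcp11l2, Tfpi and Retreg1. The highest leave-one-out adjusted p (limma) was 0.0617 for Ccbe1, without wild type replicate 4, its only loss, and 0.0811 for Ahrr, which lost its call without wild type replicates 3 or 4. Chrna2 lost its call without knockout replicate 2 or wild type replicates 3 or 4 (adjusted p up to 0.0631). Igsf1 lost it without knockout replicates 2 or 3 or wild type replicates 3 or 4 (up to 0.133), and Arc without knockout replicates 1, 2 or 3 or wild type replicates 3 or 4 (up to 0.0919). Capn3, a muscle protease, rose by 0.85 ± 0.19 and kept its call only without knockout replicates 3 or 5 or wild type replicates 1 or 2 (up to 0.147). Cenpf fell by 0.68 ± 0.15 and kept its call only without knockout replicates 5 or 6 or wild type replicates 1 or 2 (up to 0.183). Mstn, which encodes the muscle growth inhibitor myostatin, averaged 8.54 ± 2.15 against 2.16 ± 2.18 normalized counts and kept its call only without wild type replicate 2 (up to 0.162). Grin2c averaged 3.40 ± 1.44 against 12.2 ± 3.95 and kept its call only without wild type replicate 1 (up to 0.189).

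Of 39 gene lists tested with camera, 14 were called at an adjusted p of 0.05, 6 higher and 8 lower in the knockout, and 1 of them, insulin signalling, was called with an estimated correlation. Of 100 splits of the 10 libraries into 6 and 4, the real one among them, 18 called as many lists. Each of the other splits drawn called from 1 to 17 lists, so a camera call does not by itself tell the genotypes apart. For the insulin signalling, matrix and sarcomere lists no other split drawn gave as small a p. With the real split counted, as small a p came from 3 splits for macrophage markers and 5 for fibroblast markers. It came from 18 for fatty acid oxidation, 20 for oxidative phosphorylation, 20 for immediate early genes and 21 for PPAR target genes. It came from 22 for the TCA cycle, 25 for the unfolded protein response, 26 for lymphocyte markers, 31 for atrial markers and 51 for the cytosolic ribosome.

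The insulin signalling list was called lower in the knockout. It mixes members of the pathway, such as Insr and Akt2, with genes that insulin represses, such as Pck1. A lower list therefore does not show weaker insulin action. Of the 20 members, 17 had a lower mean log2 value and the median log2 fold change was -0.16. The mitochondrial biogenesis coactivator Ppargc1a fell from 1094 ± 16.5 normalized counts (SD, n = 4) to 754.6 ± 67.9 (SD, n = 6), a log2 fold change of -0.54 ± 0.07 (limma, adjusted p = 0.000316), and the insulin receptor gene Insr had a log2 fold change of -0.31 ± 0.07 (limma, adjusted p = 0.0481). Igfbp5, which encodes a binding protein of insulin-like growth factors, went the other way, from 785.2 ± 139 to 1192 ± 114 (log2 fold change 0.61 ± 0.10, adjusted p = 0.00286). Over all genes 2 members were lower and 1 higher, and adjusted over the list alone 9 were lower and 1 higher, among them the transcription factor Foxo3 (log2 fold change -0.35 ± 0.10). The list test (camera) gave adjusted p = 4.67e-08, and this was the only one of 39 lists still called with an estimated correlation, with adjusted p = 0.0336. Insr kept its call only without wild type replicate 2, and its adjusted p reached 0.183 without wild type replicate 4.

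The extracellular matrix and fibrosis list was called higher in the knockout. Of its 40 members, 37 had a higher mean log2 value and the median log2 fold change was 0.25. The small proteoglycan genes Bgn and Lum rose, Bgn from 1405 ± 90.9 to 1859 ± 190 normalized counts (log2 fold change 0.40 ± 0.07, limma adjusted p = 0.00927) and Lum from 332.9 ± 67.4 to 484.4 ± 38.3 (0.56 ± 0.10, adjusted p = 0.0112). These were the 2 members past the threshold over all genes, and adjusted over the list alone 10 were higher and 1 lower. Fibronectin (Fn1) had 398.6 ± 24.2 against 317.2 ± 44.9 normalized counts, not past the threshold over all genes (limma, adjusted p = 0.0951). Lum lost its call without wild type replicate 4 (adjusted p = 0.0625). The list was called by camera with adjusted p = 1.38e-15, and had adjusted p = 0.0947 with an estimated correlation.

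The fibroblast and macrophage marker lists were also called higher. The fibroblast list shares Dcn, Lum, Col1a1 and Col1a2 with the matrix list, so its call is not independent of that one. Fibroblast markers had a median log2 fold change of 0.19 (0.12 without wild type replicate 3), with 2 of 14 members past the threshold over all genes, Lum and the microfibril gene Mfap5 (log2 fold change 0.64 ± 0.14, limma adjusted p = 0.0481), and 4 higher adjusted over the list alone. The list test gave adjusted p = 1.22e-05 (camera), and adjusted p = 0.168 with an estimated correlation. Mfap5 kept its call only without knockout replicate 5 or wild type replicate 3 (adjusted p up to 0.157, without wild type replicate 4). Macrophage markers had a median log2 fold change of 0.29, higher in 19 of 20 members. None passed over all genes by limma (0, against 9 at an unadjusted p below 0.05, 0 by edgeR and 2 by DESeq2), and 5 were higher adjusted over the list alone. The complement genes C1qa and C1qb had 337.9 ± 38.8 against 253.3 ± 44.0 and 329 ± 40.2 against 239.8 ± 51.6 normalized counts (limma, adjusted p = 0.0951 and 0.105 over all genes), and both passed without wild type replicate 2 (0.0453 and 0.021). The integrin gene Itgam had 77.1 ± 4.56 against 54.3 ± 11.4. The macrophage list test gave adjusted p = 3.04e-08 (camera), and adjusted p = 0.0947 with an estimated correlation.

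**Figure D2:**
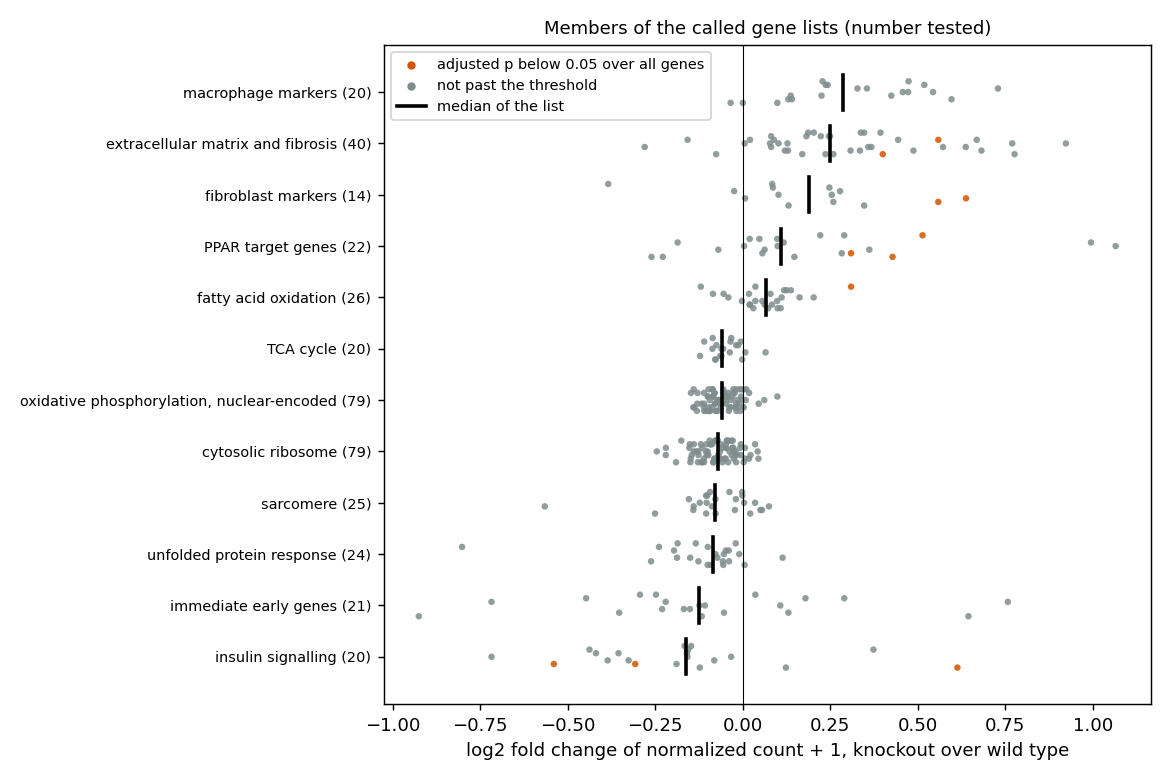
Log2 fold change of every tested member of 12 of the 14 called gene lists, the atrial and lymphocyte marker lists left out, with the number of tested members in brackets. Orange points passed an adjusted p of 0.05 over all genes and black bars give the list medians, which run from -0.16 for insulin signalling to 0.29 for macrophage markers.

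The PPAR target and fatty acid oxidation lists were called higher by camera, and few of their members passed. Fabp3, the fatty acid binding protein of heart muscle, rose from 22108 ± 1553 to 27397 ± 1781 normalized counts (log2 fold change 0.31 ± 0.06, limma adjusted p = 0.0112). The lipid droplet genes Cidea (0.51 ± 0.11, adjusted p = 0.0365) and Plin2 (0.43 ± 0.10, adjusted p = 0.0481) also rose. In the list of PPAR target genes these were the 3 of 22 members past the threshold over all genes, and adjusted over the list alone 3 were higher and 1 lower, the lipase gene Lpl (47190 ± 3379 in wild type, 41517 ± 3297 in the knockout). Of the 3 that passed over all genes, Cidea lies 0.486 Mb from Mc4r, so an effect of alleles linked to the knockout allele stays possible for it. Of the 26 fatty acid oxidation genes Fabp3 alone passed, over all genes and adjusted over the list alone. The camera test gave adjusted p = 0.000121 for the PPAR list and 0.00277 for fatty acid oxidation, and adjusted p = 0.701 for both with an estimated correlation. The mean log2 value of the PPAR list was 10.24 and 10.25 in wild type replicates 1 and 2, within the knockout range of 10.08 to 10.44. Only wild type replicates 3 (9.812) and 4 (9.894) lay below that range. Leaving out 1 library raised the adjusted p of the PPAR list to at most 0.0432 (camera). Fabp3 lost its call without wild type replicates 3 (0.0531) or 4 (0.0636), Cidea and Plin2 kept theirs only without knockout replicate 5 or wild type replicates 1 or 2 (up to 0.183 each), and fatty acid oxidation lost its call without wild type replicates 3 or 4 (up to 0.0746).

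The lists of nuclear-encoded oxidative phosphorylation genes and of the TCA cycle were called lower by camera, with no member past the threshold. Their median log2 fold changes were -0.06 over 79 members, 70 of them lower, and -0.06 over 20 members, 18 of them lower (TCA cycle -0.03 without wild type replicate 3). The ATP synthase gene Atp5b had 37674 ± 1706 against 40641 ± 794 normalized counts and citrate synthase (Cs) 11230 ± 547 against 12214 ± 506. No member passed by limma, over all genes or adjusted over the list alone, by edgeR or by DESeq2 (0 by each), and 2 and 1 had an unadjusted p below 0.05. The camera calls (adjusted p = 6.51e-05 and 0.0495) were lost with an estimated correlation, with adjusted p = 0.701 for both. Without wild type replicate 2 and knockout replicate 5 the calls were lost as well (0.0787 and 0.138). The TCA cycle call was also lost without knockout replicates 1, 3 or 5 or wild type replicates 1, 2 or 3 (adjusted p up to 0.255), and in 5 settings of filter, scaling, library weights and replicate block (up to 0.166). The glucose use and glycolysis list was not called (camera, adjusted p = 0.76). None of its 26 members passed over all genes by limma (0, against 5 at an unadjusted p below 0.05, 0 by edgeR and 1 by DESeq2), and adjusted over the list alone 3 were lower and 1 higher. The glycolytic regulator Pfkfb2 had 1075 ± 77.0 against 1343 ± 172, and passed without wild type replicate 2 (adjusted p = 0.00252).

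Sarcomere genes had a median log2 fold change of -0.08, and 19 of 25 members had a lower mean log2 value (median of the sarcomere list -0.05 without wild type replicate 3). The cardiac myosin light chain kinase Mylk3 had 3904 ± 159 against 4647 ± 300 normalized counts and was the 1 member that passed adjusted over the list alone. Over all genes its adjusted p was 0.0564 and no member passed by limma (0, against 3 at an unadjusted p below 0.05, 1 by edgeR and 2 by DESeq2). Myom2 had 6675 ± 1090 against 9861 ± 1613 (limma, adjusted p = 0.221). It was the member that passed by edgeR, and by DESeq2 it passed together with Mylk3. Without wild type replicate 2, Mylk3 passed (adjusted p = 0.0221). The sarcomere list was called by camera (adjusted p = 0.00561), and had adjusted p = 0.327 with an estimated correlation and 0.0738 after quantile normalization, where its median log2 fold change was -0.00223.

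The fetal and stress gene programme, a set of genes that hypertrophied or failing ventricle often expresses, was not called (camera, adjusted p = 0.0547). Its median log2 fold change was 0.06 (0.04 without knockout replicate 3, 0.09 without wild type replicate 1 and 0.03 without wild type replicate 2), and 1 of 25 members passed over all genes and 3 adjusted over the list alone. The LIM protein gene Fhl1 rose from 833.3 ± 41.0 to 1111 ± 131 normalized counts (log2 fold change 0.41 ± 0.08, limma adjusted p = 0.0114), while the calcineurin regulator Rcan1 had 795.2 ± 162 against 571.6 ± 54.7 and Xirp2 6636 ± 439 against 5446 ± 903. Beta myosin heavy chain (Myh7), picked out after its values were seen, had 1520 ± 322 against 1034 ± 531 (limma, adjusted p = 0.616), and the natriuretic peptide genes Nppa and Nppb, picked out likewise, had 724.5 ± 349 against 777.1 ± 378 and 623.5 ± 257 against 892.9 ± 439 (adjusted p = 0.963 and 0.788). Fhl1 lost its call without knockout replicate 2 (adjusted p = 0.051) or wild type replicates 1 (0.0523) or 4 (0.0617), and Rcan1 passed without knockout replicate 5 (0.0291). The list was called without knockout replicates 1, 4 or 6 or wild type replicates 1 or 4, with adjusted p as low as 0.00952.

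The calcium handling and ion channel list was not called (camera, adjusted p = 0.98). Kcnip2, the subunit that sets the transient outward potassium current, fell from 1388 ± 128 to 1021 ± 44.0 normalized counts (log2 fold change -0.44 ± 0.07, limma adjusted p = 0.00198). It was the 1 of 31 members past the threshold over all genes, and adjusted over the list alone 3 were lower and 1 higher. Among the others were the pacemaker channel genes Hcn2 (118 ± 15.0 against 156 ± 14.3) and Hcn4 (49.4 ± 10.9 against 30.2 ± 14.1). Hcn4 passed over all genes without wild type replicate 1 (limma, adjusted p = 0.0171). The test for change in either direction (fry, mixed) gave adjusted p = 3.33e-05. That test called 14 of the 39 lists. Among them were others that camera did not call, such as adrenergic and melanocortin signalling and autophagy and proteasome (fry, mixed, adjusted p = 0.00047 for both).

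The cytosolic ribosome, unfolded protein response and immediate early gene lists were called lower by camera (adjusted p = 1.28e-05, 0.00582 and 0.0244), each with adjusted p = 0.701 with an estimated correlation. Their median log2 fold changes were -0.07, -0.08 and -0.12. The median of the unfolded protein response list was -0.16 without wild type replicate 2 and -0.02 without wild type replicate 3. That of the immediate early genes was -0.06 without wild type replicate 2, -0.20 without wild type replicate 1 and -0.20 without wild type replicate 4, and that of the cytosolic ribosome -0.11 without wild type replicate 1. No member of the 3 lists passed over all genes by limma, edgeR or DESeq2 (0 by each), and 1, 2 and 5 had an unadjusted p below 0.05. Adjusted over the list alone, 2 immediate early genes were lower, Nr4a1 (38.9 ± 10.3 against 63.8 ± 12.6 normalized counts) and Btg2 (191.7 ± 17.9 against 245.8 ± 33.5). Without wild type replicate 2, the library with T-cell transcripts, the ribosome list turned higher, with a median log2 fold change of 0.0054 (adjusted p = 0.783), and it was higher without that library and knockout replicate 5 too (0.39). Among the other losses were the unfolded protein response call without wild type replicate 3 (0.339) and the immediate early call without knockout replicates 2 or 5 or wild type replicates 2 or 3 (up to 0.288), with camera on ranks (0.0649), with library weights (0.119) and with the replicate block (0.175). The directional fry test called none of the 3 lists (adjusted p = 0.634, 0.526 and 0.526).

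Some libraries held transcripts of other cells or tissues. In wild type replicate 2 the T-cell genes Cd4 and Cd3e reached 252.7 and 106.5 normalized counts, against at most 15.4 in each of the other 9 libraries, and Xist reached 133.6 against at most 7.92, while the Y-linked gene Ddx3y stood at 340.3 against 387.5 to 483.2 and Uty at 108.3 against 119.2 to 177.2. The Y-linked genes Eif2s3y (350.2 against 315 to 474.9) and Kdm5d (123.7 against 108.5 to 149.5) lay within the range of the others there, and the heart muscle gene Myh6 was the highest of all 10 libraries (179649). Uty, Eif2s3y, Kdm5d and Myh6 were picked after their values were seen. The lymphocyte marker list was called lower in the knockout (camera, adjusted p = 0.0234), and the call was lost without wild type replicate 2 (adjusted p = 0.694), knockout replicate 3 or knockout replicate 4, with smaller pseudocounts (up to 0.12) and with library weights (0.117). In knockout replicate 5 the atrial genes Myl7 and Sln reached 720.2 and 170.2 normalized counts, in knockout replicate 6 134.3 and 22.2, and in the other 8 libraries at most 63.0 and 3.85. The atrial list was called higher (adjusted p = 0.0189) and lost the call without knockout replicates 5 (0.173) or 6 or wild type replicates 2 or 3, with library weights (0.117) and with the replicate block (0.614). Both lists had adjusted p = 0.701 with an estimated correlation, and 0 members passed by limma, edgeR or DESeq2 or at an unadjusted p below 0.05. Without wild type replicate 2 and knockout replicate 5, 167 genes passed (limma; 105 higher and 62 lower, 62 of them shared with the 67), and the insulin signalling, matrix, macrophage, fibroblast and PPAR lists were still called in the same direction (camera, adjusted p = 2.53e-07, 8.13e-12, 1.09e-05, 0.000687 and 9.96e-09), as were fatty acid oxidation, sarcomere and unfolded protein response (3.8e-06, 0.00684 and 4.2e-05). Of these 8 lists insulin signalling alone was called with an estimated correlation over all 10 libraries (adjusted p = 0.0336), and the others had adjusted p of 0.0947 to 0.701. The calls of oxidative phosphorylation (0.0787), the TCA cycle (0.138), atrial (0.39) and lymphocyte markers (0.426) were lost there. So was that of immediate early genes (0.566, with a median of 0.0533 against a test direction of lower), and the cytosolic ribosome list turned higher (0.39). Newly called there by camera were mitochondrial ribosome (0.00976) and antioxidant genes (0.0237), both higher. Erythrocyte (0.0114) and smooth muscle markers (0.0449) were newly called lower. With an estimated correlation over all 10 libraries these newly called lists had adjusted p of 0.701 to 0.754 (camera).

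**Figure D3:**
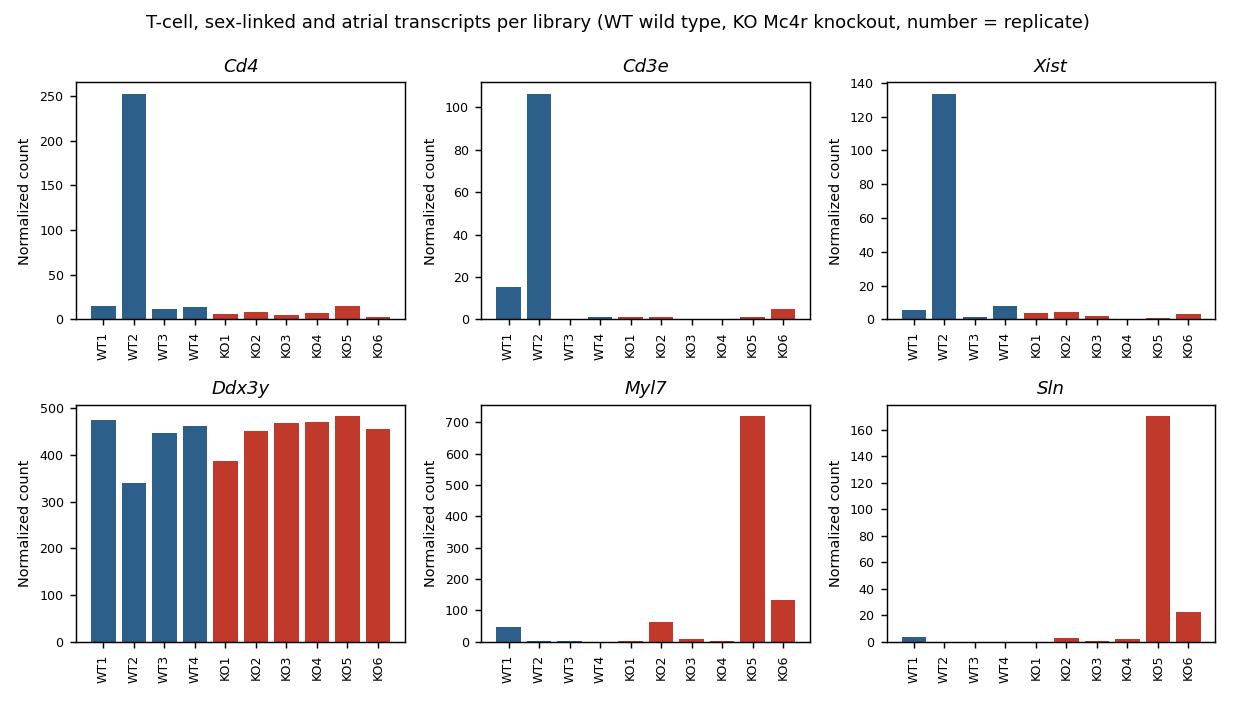
Normalized counts per library of a pair of T-cell genes (Cd4, Cd3e), the female-specific Xist, the Y-linked Ddx3y and a pair of atrial genes (Myl7, Sln); bars are single libraries, blue for wild type and red for Mc4r knockout. Wild type replicate 2 stands apart for Cd4 (252.7) and Xist (133.6), and knockout replicate 5 for Myl7 (720.2) and Sln (170.2).

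Called genes lay near Mc4r more often than elsewhere. Within 10 Mb of Mc4r on chromosome 18, 4 of 102 tested genes passed, against 63 of 14255 elsewhere, an odds ratio of 9.19 (95% interval 2.38 to 25.5; Fisher's exact test, two-sided, p = 0.00131). The odds ratio was 5.06 without wild type replicate 2 and 5.92 without knockout replicate 6. Without wild type replicate 4 a single gene near Mc4r passed and the excess was not significant (5.63, Fisher's exact test, p = 0.169). The mitochondrial protease gene Afg3l2 (67404764 to 67449192) had the smallest p of all genes, with 2031 ± 153 against 1380 ± 63.4 normalized counts (log2 fold change 0.55 ± 0.07, limma adjusted p = 0.00015). Cidea (67343564 to 67367794) and the kinase gene Alpk2 (65265529 to 65393888; 0.34 ± 0.07, adjusted p = 0.0278) were also higher, and Ccbe1, a secreted protein of lymphatic vessel growth (66056855 to 66291838), was lower (-0.80 ± 0.15, adjusted p = 0.0112). Alpk2 lost its call without knockout replicates 1, 2 or 6 or wild type replicates 3 or 4 (up to 0.167) and Ccbe1 without wild type replicate 4 (0.0617). With an unadjusted p below 0.01 in place of the adjusted threshold the odds ratio was 1.82 (Fisher's exact test, p = 0.157). The size of the odds ratio also depended on the window, at 22.6 for 5 Mb and 5.94 for 20 Mb with the adjusted threshold.

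**Figure D4:**
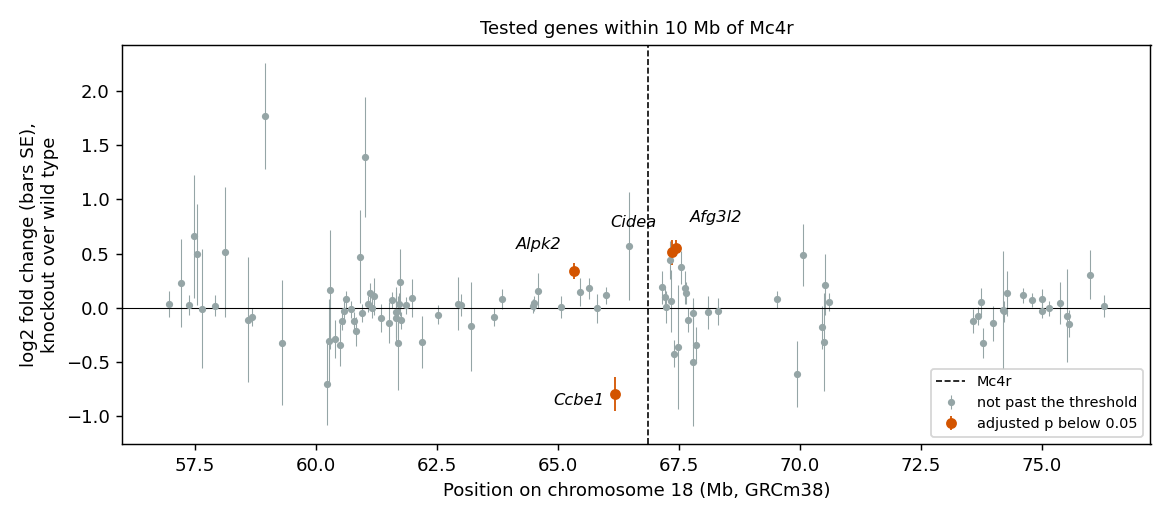
Log2 fold change (knockout over wild type, bars SE) of the 102 tested genes within 10 Mb of Mc4r against their position in Mb on chromosome 18 of GRCm38; the dashed line marks Mc4r. The 4 genes past an adjusted p of 0.05 (orange) are Alpk2, Ccbe1, Cidea and Afg3l2, and 3 of them are higher in the knockout.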

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

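The tests that weigh explanations here were chosen after the results were seen, and so were the splits of all genes and of all lists, while the splits of single lists were set before their outcome was known.

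Wild type replicate 2 stood apart from the other 9 libraries: 71 genes were at least 8 times above every other library in it, against 1 in knockout replicate 5 and 0 in each of the others, and its 8 T-cell receptor signalling genes summed to 1298 normalized counts against a mean of 28.2 (Cd4 252.7, and Tcf7, outside that list and picked after its values were seen, 476.6). Of those 8 genes, 5 are also in a list fixed beforehand and 7 average at least 1 in the other libraries, as holds for the 8 B-cell and CD8 T-cell markers. Blood or lymphoid tissue of the same male animal is argued against by those markers, which summed to 1.32 times the mean of the others while T-cell genes stood at 46.1 times, and by Xist, at 16.9 times its highest level elsewhere. RNA of female CD4 T cells from outside this heart may account for these values, though signs of a dilution of the heart RNA were mixed, with the Y-linked sum low (922.5 against at least 1052.4) and Ddx3y and Uty below every other library, but Eif2s3y and Kdm5d within the range of the others and Myh6 the highest of all 10; its route was not tested, and neither was a biological explanation. This library alone does not make the calls, since 61 of the 67 genes were still called without it. Wild type replicate 3 also stood apart, at -49.3 on the second principal component (14.5% of the variance) against -9.15 to 19.9 in the others. It had the fewest reads (4145033). The fit without wild type replicate 2 and knockout replicate 5 kept it. With wild type replicate 3 alone left out, 31 genes passed, 28 of them among the 67.

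Genes within 10 Mb of Mc4r were called more often than others, with an odds ratio of 9.19, which was 5.06 without wild type replicate 2, 5.92 without knockout replicate 6 and, with 1 gene left near Mc4r, 5.63 without wild type replicate 4 (Fisher's exact test, p = 0.169). Loss of variant reads in alignment is argued against for the 3 genes that were higher in the knockout. For Ccbe1, at -0.80 on the log2 scale, it cannot be told apart from a lower level, since the reads were not used here. Alleles of another strain linked to the knockout allele may account for the excess, which rests on 4 genes. The label gives C57BL6/J for all libraries, the strain of the targeted cells was not given there, and an effect of the loss of Mc4r on its neighbours stays open.

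The insulin signalling list was called lower in the knockout. A trend with GC content or length is argued against as the whole cause by adjusted p = 1.08e-07 with that trend removed, and lymphocyte RNA in wild type replicate 2 by adjusted p = 1.68e-07 without that library (0.0336 with an estimated correlation and all libraries). Lower transcription of FoxO targets, genes that insulin represses, may be part of the pattern: 14 FoxO targets outside the list and the calls were lower as a set (camera, p = 0.0081, and p = 0.0227 with an estimated correlation), 10 of them lower, with a median log2 fold change of -0.09. This is a hypothesis found and tested on the same data, FoxO protein and insulin levels were not used here, and other effects of the genotype stay open.

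Of the 210 possible splits of the libraries into 6 and 4, 100 were drawn. The 67 genes (highest other split 14), the 42 higher (6) and the 25 lower (8) were each reached by 1 split, the real one. This argues against chance for these counts but does not exclude it, since 1 in 100 is the smallest share these splits can give. For the number of lists, 14 against up to 17 and reached by 18 splits, the splits do not argue against chance. By the same permutation of the libraries, the insulin signalling list (camera p = 3.59e-09, smallest other 1.93e-06) and the matrix list (3.54e-17, smallest other 4.32e-17) were each reached by 1 split, the real one, and the macrophage list (1.56e-09, smallest other 2.75e-10) by 3. For each of these lists taken alone the splits argue against chance, narrowly for the matrix list, but do not exclude it. Adjusted over the 39 lists, the shares of splits were 0.13 for insulin signalling and matrix and 0.292 for macrophage markers. So few as 100 splits cannot give a small share after that adjustment. With an estimated correlation only insulin signalling kept its call (camera, adjusted p = 0.0336, against 0.0947 for the other 2).

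Dixon's ratio compared the highest and lowest library of each group with its neighbour, for each gene named, each called list and the read totals. It singled out 24 of 176 values. Chance gives about 1 in 20 groups, but the genes include some named because they stood out in 1 library (Cd4, Cd3e, Xist, Tcf7, Myl7 and Sln), so that share does not apply to the count. In wild type replicate 2, Cd4 (252.7), Cd3e (106.5), Xist (133.6), Tcf7 (476.6) and Mstn (5.42) were above the other wild type libraries, as was the ribosome list (mean log2 value 10.58), and Pfkfb2 (1088) was below. In knockout replicate 5, Myl7 (720.2), Sln (170.2) and Hcn4 (70.9) were above the other knockouts and Scn4b (875.2) and Fabp3 (23870) below. In wild type replicate 1, Myl7 (48.1), Sln (3.85), the atrial list (6.14) and Mc4r (1.92) were above the group and Slc7a1 (331) below. Among the other knockouts, Fn1 was low (350.9) and the unfolded protein response list high (8.38) in replicate 4, Cd3e high in replicate 6 (5.05), Ddx3y low in replicate 1 (387.5), and in replicate 3 the sarcomere list low (12.95) and the read total high (6408864). In wild type replicate 4 the macrophage list was high (6.35).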

How the results depend on the processing

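The alternatives with edgeR, DESeq2 and the removal of GC and length trends were chosen after the data were seen. So were the fit without wild type replicate 2 and knockout replicate 5, and each library left out for the genes near Mc4r. Of these, edgeR had been planned for a file of raw counts. The count of 67 genes, 42 higher and 25 lower, stayed within 1.5 times its value under other pseudocounts, filters and normalizations (45 to 70 genes). With a block for the replicate number 52 genes passed, 35 of them among the 67. The labels do not say that the numbers pair the libraries. The correlations of equally numbered libraries (-0.0601, -0.0319, -0.0599 and -0.00349) gave no sign of pairing but cannot exclude it. Without limma's trend and robust steps 0 genes passed (0 higher, 0 lower), against 1290 at an unadjusted p below 0.05, 50 by edgeR and 122 by DESeq2. Library weights gave 118 (71 and 47), DESeq2 122 (75 and 47), removal of GC and length trends 112 (66 and 46), and that removal with the replicate block 103 (65 and 38). edgeR without wild type replicate 2 gave 105 genes, 51 of them lower, and limma without wild type replicate 2 and knockout replicate 5 gave 167 (105 and 62). Leaving out 1 library gave 26 to 118 genes, 16 to 69 higher and 10 to 49 lower, lowest without wild type replicate 4 (for higher genes also knockout replicate 2) and highest without wild type replicate 2, and 19 of the 67 genes passed in every such run. The cause of these shifts was not tested. Camera called 14 lists, 1 with an estimated correlation, and fry 2 by its directional test, while leaving out 1 library gave 10 to 17. The odds ratio near Mc4r was 22.6 and 5.94 with windows of 5 and 20 Mb and ran from 5.06 without wild type replicate 2 to 10.5 without knockout replicates 2 or 3 (5.63, p = 0.169, without wild type replicate 4), and was 1.82 (Fisher's exact test, p = 0.157) at an unadjusted p below 0.01, which admits 474 genes elsewhere. A permutation statistic per gene gave 1224 genes at an unadjusted p below 0.05, against 1403. For the genes taken by the naming rule, 2282 comparisons of a setting with the reported result kept direction and side of the threshold, 207 lost the call and 58 gained it. The 1 that changed sign was Atp5a1, not called in either, at 0.048 after quantile normalization. For the 14 called lists, 310 comparisons kept both, 66 lost the call and 2 reversed. Both reversals were of the cytosolic ribosome list, whose median log2 fold change was 0.013 without wild type replicate 2 and knockout replicate 5 and ran from -0.11 without wild type replicate 1 to 0.0054 without wild type replicate 2. Of the 25 lists not called, 595 comparisons kept both, 29 gained a call and 49 changed direction. A fit with Xist as covariate was not run, because Xist did not split the libraries as its condition required. Depth limits the weakest genes: with at most 2 reads of Mc4r per library, no difference in it was detectable.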

Other observations

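The lists and genes of the next 2 paragraphs were chosen after their values were seen, as was the test of FoxO targets. In the adrenergic and melanocortin signalling list, Grk5, the kinase that desensitizes G-protein-coupled receptors, rose from 258.2 ± 16.3 normalized counts (SD, n = 4) to 365.3 ± 49.0 (SD, n = 6), a log2 fold change of 0.49 ± 0.10 (SE; limma, adjusted p = 0.013). It was the 1 of 20 members past the threshold over all genes, and adjusted over the list alone 2 were higher and 2 lower. The list was not called (camera, adjusted p = 0.518). Of the 35 antioxidant and NRF2 target genes none passed over all genes by limma (0, against 4 at an unadjusted p below 0.05, 0 by edgeR and 3 by DESeq2). Adjusted over the list alone 3 were higher, the extracellular superoxide dismutase Sod3 (300.3 ± 37.7 against 224.9 ± 26.1), the quinone reductase Nqo1 (585.5 ± 86.4 against 438.2 ± 43.1) and catalase (Cat, 2367 ± 73.9 against 2043 ± 150). That list was not called either (camera, adjusted p = 0.262), but was called higher without wild type replicate 2 and knockout replicate 5 (camera, 0.0237). The test for change in either direction called it over all libraries (fry, mixed, adjusted p = 0.015). Grk5 lost its call without knockout replicate 2 or wild type replicate 4 (adjusted p up to 0.0617).

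Single genes of muscle and nutrient control also changed. Myl1, a myosin light chain of fast skeletal muscle, rose by 0.54 ± 0.10 on the log2 scale (limma, adjusted p = 0.00927). It was the 1 of 10 tested skeletal muscle markers past the threshold over all genes. Of those markers 7 were higher and 3 lower, and their list was not called (camera, adjusted p = 0.151). The folliculin gene Flcn, a regulator of nutrient sensing at the lysosome, had a log2 fold change of -0.45 ± 0.08 (adjusted p = 0.00381). Both kept their call whichever library was left out. Corin, the protease that activates natriuretic peptides, was lower, at 1359 ± 149 against 1755 ± 99.2 normalized counts (limma, adjusted p = 0.0184), and lost its call without knockout replicate 2 or wild type replicates 3 or 4 (up to 0.0636). The autophagy gene Gabarapl1 was lower as well (log2 fold change -0.32 ± 0.07, adjusted p = 0.0268), and lost its call without knockout replicates 1 or 2 or wild type replicates 1, 3 or 4 (up to 0.0944). It was the 1 of 23 autophagy and proteasome genes past the threshold over all genes. Of those genes 11 were higher and 12 lower, and their list was not called (camera, adjusted p = 0.612).

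A list of 22 FoxO target genes, 14 of which are also in a list fixed before the data were examined, had a median log2 fold change of -0.13, with 18 genes lower in the knockout (camera, p = 2.17e-08, and p = 0.000319 with an estimated correlation). That p draws on members that are called or in the insulin signalling list, so it is not independent of them.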
